A study of Mus musculus with 18 samples.

How the data were processed

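Gene expression was measured on Affymetrix mouse whole-genome arrays in dopamine neurons taken by laser capture from the substantia nigra (SN) and the ventral tegmental area (VTA) of adult mice. Per the labels' protocols, RNA was extracted with a spin-column kit, amplified and copied into cDNA with the WT-Ovation Pico system, fragmented and biotin labelled. Groups and replicate numbers were taken from the sample titles, which gave 6 groups of 3 arrays. The labels call the replicates biological and do not state whether an SN array and a VTA array came from the same mouse, nor how many mice each array holds. They also do not state how dopamine neurons were recognised before capture.

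The deposited values are log2 signals of 45101 probe sets on 18 arrays. The authors log2 transformed and RMA normalised them with GeneSpring GX 10.0, per the series' design text, and RMA is also named in the submitters' processing notes. A checked property that no source states is centring: the median of every probe set over the 18 arrays is 0 to within 5e-07. The deposited log2 values are therefore differences from each probe set's own median, and hold no absolute level and no detection call. Values ran from -5.02 to 6.73 with 0 missing, array medians lay between -0.008 and 0.016, and 0 arrays were identical. Background correction and filtering by the authors are not given in the sources used here. Because no level is known, no filter on dim probe sets was possible, and the number of arrays limits the precision.

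Probe sets were named through the platform's annotation table, which can be old. It gave 1 gene symbol to 34945 probe sets, several to 932 and none to 9211, and 64 control probe sets, which overlap the unnamed ones, were left out even where they had a symbol. The 34945 probe sets covered 18193 genes, of which 9010 had several probe sets. Of the symbols, 99.74% were found in a RefSeq gene table of the assembly GRCm38.p6. That table was used only for names and for which genes neighbour each other, and no coordinates are reported because the sources name no genome build. Before the data were examined, the plan was to use the probe set of highest mean level per gene and to leave out the genes of lowest level, with the mean of a gene's probe sets and no filter as the stated fallback if values were centred. The fallback was used throughout.

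Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model of 6 group means over all 18 arrays, with 12 residual degrees of freedom and 4.06 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over 18193 genes within a comparison, two-sided, with a threshold of 0.05. Planned were 11 comparisons: each duration of MPTP against saline in each region, 10 against 2 days in each region, VTA against SN at each treatment, and the difference of the VTA and SN responses at each duration. Errors of differences are standard errors (SE) from this model, and errors of group means are standard deviations (SD). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

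Before the data were examined, 29 gene lists with 710 genes were fixed. They covered dopamine neuron identity, genes enriched in SN or VTA neurons in earlier work, mitochondrial complexes, antioxidant genes, apoptosis, the unfolded protein response, heat shock chaperones, the proteasome, immediate early genes, neurotrophic factors, interferon-stimulated genes, synaptic vesicles, ion channels, familial Parkinson disease genes, cholesterol synthesis, axon guidance, lysosome and autophagy, and ribosomal proteins. A further set held markers of astrocytes, microglia, oligodendrocytes and their precursors, endothelium, GABA neurons, other neurons, erythrocytes, and ependyma with choroid plexus. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Means of a list per array were also compared by exact permutation of the arrays, where 10 splits of 3 against 3 arrays give a smallest p of 0.1.

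The rule for named genes was also fixed before the data were examined. It takes, per comparison, the 8 largest rises and 8 largest falls among genes that passed without overlap between arrays, up to 2 members of each list each way, and, where fewer than 5 genes passed, the 5 genes of smallest p each way, given as not passing. Th, Slc6a3, Slc18a2 and Ddc, and regional marker genes in comparisons between regions, are always eligible, and a further gene that the rule names is not reported here. Symbols of clones and predicted genes are skipped by the rule. AA388235 falls under that exclusion and was named after its values were seen, because the counts it belongs to are small. For length, not every eligible gene is printed.

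Alternatives fixed in advance were all probe sets tested singly, a fit of only the groups compared, centring of each array on its median, a repeated quantile normalisation, array weights, the replicate number as a block, leaving out each array in turn, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were robust eBayes, the probe set of largest SD per gene, omission of the 2 arrays of widest spread, a random block of treatment by replicate number (duplicateCorrelation, consensus 0.187), and comparisons pooled over both regions. Responses sharing control arrays were set beside 100 simulations of unchanged groups. After the data were seen, 100 further simulations let SN and VTA arrays of the same number correlate as observed.

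Whether replicate numbers pair SN with VTA arrays was tested by correlating their deviations from the group means. Among 10 day arrays the correlations were 0.324, 0.281 and 0.399, above 0.1 for every pair. The comparison of regions after 10 days was therefore also run with the numbers as pairs, while the values given for it come from the model without pairs. With the number as a block, that comparison again had 0 genes past the threshold, and no call of a gene list changed.

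The code was tested on simulated data for SN after 2 days of MPTP against saline, with 200 of 18193 genes changed in each of 5 draws. It recovered 68.8% of 250 genes changed by 1 on the log2 scale, 98.4% of those changed by 2, and 99.6% of those changed by 3 and of those changed by 4, with 26 false calls in all. A list shifted by 0.5 was called in 5 of 5 draws, and 0 of 140 tests of unshifted lists were called. The simulated genes were drawn independently, so these draws cannot show how list calls behave where members are correlated. The recovery of genes holds for 200 changed genes and may differ where fewer change.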

Results

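Dopamine neurons were collected by laser capture from the substantia nigra (SN), whose dopamine neurons are lost in Parkinson disease, and from the adjoining ventral tegmental area (VTA), whose dopamine neurons are less vulnerable. The C57Bl/6 mice carried green fluorescent protein under human tyrosine hydroxylase sequences. They received MPTP, which is converted to a toxin that dopamine neurons take up and that inhibits mitochondrial complex I, at 4 mg/kg for 2 or 10 days, or saline for 10 days, and were killed 7 days after the last injection. Each region had 3 arrays per treatment, 18 in all, so the 2 day groups differ from their controls also in the number of days of injection. Sample descriptions call the controls untreated, whereas the treatment protocol and the design text give them saline. If they were not injected, every difference from control also holds the effect of injection. The series asks whether VTA neurons answer MPTP differently from SN neurons.

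The labels do not tie arrays to mice, and SN and VTA arrays may come from the same mice. In that case p-values of averages over both regions may be too small, and those of differences between regions too large. The labels do not state how neurons were recognised. If the fluorescent reporter was used, the level of Th, the tyrosine hydroxylase gene, is no finding between regions. The median absolute deviation of centred log2 signals was 0.349 on SN control array 1 and 0.399 on array 1 of VTA after 2 days, and 0.182 to 0.302 on the other arrays. Correlations between arrays over all probe sets ran from -0.225 to 0.377. The first principal component held 16.9% of the variance, with array 1 of VTA after 2 days at 59.6, and the second 13.4%, with SN control array 1 at 45.2.

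In saline-treated mice, genes known to be enriched in VTA dopamine neurons had higher signals in VTA, and genes known to be enriched in SN neurons had higher signals in SN. The 22 VTA-enriched genes had a median difference of 0.36 on the log2 scale, with 16 higher in VTA, and the 17 SN-enriched genes one of -0.29, with 16 lower in VTA (camera, adjusted p = 0.000257 for each; adjusted p = 0.248 and adjusted p = 0.675 with an estimated correlation). Exact permutation p of the list means were 0.2 and 0.5, and 0.8 for dopamine neuron identity genes. Among VTA-enriched genes, the difference was 1.23 ± 0.36 (SE, 3 arrays per group) for Tacr3, which encodes the neurokinin 3 receptor, 0.80 ± 0.32 for the homeobox gene Otx2, and 0.71 ± 0.20 for the calretinin gene Calb2. It was 0.23 ± 0.22 for the calbindin gene Calb1, whose probe sets ranged from -0.26 to 0.44, and 1.09 ± 0.70 for the neuropeptide gene Adcyap1. Among SN-enriched genes, it was -0.43 ± 0.17 for the transcription factor gene Sox6, -0.94 ± 0.30 for the calcium pump gene Atp2a3 and -0.59 ± 0.38 for Aldh1a1, a retinaldehyde dehydrogenase. The dopamine transporter gene Slc6a3 was at -0.60 ± 0.37 and Th at -0.45 ± 0.52, and without VTA control array 1 they were at -0.088 and 0.205. Without that array Aldh1a1 was at -0.25 and Atp2a3 at -0.57. With 1 array left out, Calb1 ran from 0.021 to 0.39 and Adcyap1 from 0.675 to 1.82.

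No single gene passed between control regions. Limma called 0 of 18193 genes, with 794 at an unadjusted p under 0.05 where 910 are due to chance, and each alternative setting also gave 0. The smallest adjusted p was 0.224, for Zwilch, a kinetochore gene, at -1.81 ± 0.31 and for the zinc finger gene Zfp112 at -0.85 ± 0.14, each lower on all 3 VTA arrays. Adjusted over the list alone, 2 VTA-enriched genes passed and 0 of the SN-enriched genes. The 26 genes of dopamine neuron identity had a median of -0.275, with 19 lower in VTA (adjusted p = 0.0491; adjusted p = 0.845 with an estimated correlation). Markers of other cells moved with region: astrocyte genes had a median of 0.15, with 16 of 17 higher in VTA (adjusted p = 0.0166; adjusted p = 0.675 with an estimated correlation), and oligodendrocyte precursor genes one of 0.099, with 6 of 7 higher (adjusted p = 0.0413; adjusted p = 0.509 with an estimated correlation). Without SN control array 1 the calls of the SN-enriched (-0.14), identity (-0.061) and astrocyte (0.11) lists ended, and without VTA control array 1 those of the SN-enriched (-0.17), identity (0.15, turned in sign), astrocyte (0.068) and precursor (0.13) lists. The precursor call also ended without SN control array 2 (0.039). Without SN control array 1 the VTA-enriched list kept its call at a median of 0.21. The SN and VTA arrays may share mice.

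After 2 days of MPTP, the genes that define dopamine neurons fell as a group in SN. Of 26 identity genes 25 were lower than in saline controls, with a median difference of -0.96, and the mean of the list per array went from 0.53 ± 0.28 (SD, n = 3) in controls to -0.34 ± 0.15. Th was at -1.29 ± 0.52 (SE), Slc6a3 at -0.96 ± 0.37, the vesicular monoamine transporter gene Slc18a2 at -0.995 ± 0.43 and the aromatic amino acid decarboxylase gene Ddc at -0.90 ± 0.31. Ret, the receptor through which GDNF signals, was at -1.27 ± 0.32, and Foxa1, a transcription factor of midbrain dopamine neurons, at -1.10 ± 0.30. The 17 SN-enriched genes fell as well, with a median of -0.69 and 16 lower, among them the neurotensin receptor gene Ntsr1 at -1.33 ± 0.48. In each of these 7 genes the arrays of the 2 groups did not overlap, which chance gives in 10% of genes. Ret, Foxa1 and Ntsr1 were named for their small p in this comparison. All 7 were read on the same arrays and moved together, so they are not independent support.

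The identity list was called by camera (adjusted p = 6.89e-14), and not with an estimated correlation (adjusted p = 0.246) or by fry (adjusted p = 0.124). The exact permutation p of its mean was 0.1, the smallest that 10 splits of 3 against 3 arrays allow. Of its members 0 passed over all genes and 8, all lower, adjusted over the list alone. The SN-enriched list had an adjusted p = 2.43e-07 (adjusted p = 0.279 with an estimated correlation). Leaving out any 1 array kept both calls, with identity medians between -1.10 and -0.80. The SN-enriched median was -0.38 without SN control array 1.

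**Figure D1:**
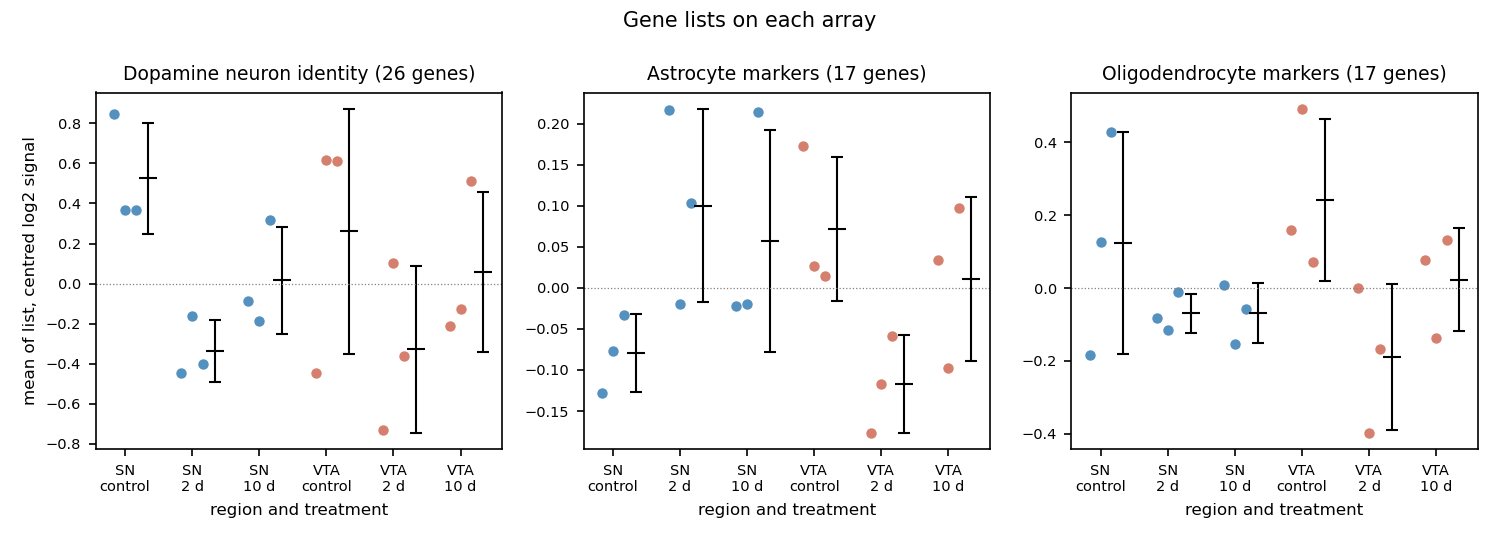
Mean of the centred log2 signals of a gene list on each array (vertical axis, log2 units) for the 6 groups of region and treatment (horizontal axis), in panels for 26 dopamine neuron identity genes, 17 astrocyte genes and 17 oligodendrocyte genes. Points are arrays and black bars are means ± SD of 3 arrays; in SN the identity means lie between 0.37 and 0.85 in controls and between -0.45 and -0.16 after 2 days of MPTP.

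Other groups also moved in SN after 2 days. Cholesterol synthesis genes fell, with a median of -0.22 and 17 of 19 lower (adjusted p = 0.000174; adjusted p = 0.279 with an estimated correlation), with the sterol enzyme gene Hsd17b7 at -0.49 ± 0.16 and Insig1, a regulator of sterol synthesis, at -0.415 ± 0.14 (-0.26 without SN control array 1). VTA-enriched genes rose, with a median of 0.215 and 18 of 22 higher (adjusted p = 0.000714; adjusted p = 0.246 with an estimated correlation), with the semaphorin receptor gene Plxnc1 at 0.63 ± 0.15 and 1 member past the threshold adjusted over the list alone. Immediate early genes rose by a median of 0.19, with 18 of 22 higher (adjusted p = 0.0301; adjusted p = 0.755 with an estimated correlation), with the orphan nuclear receptor gene Nr4a1 at 0.74 ± 0.26. Ribosomal protein genes were at 0.057, with 32 of 48 higher (adjusted p = 0.0317; adjusted p = 0.755 with an estimated correlation). Astrocyte markers rose by a median of 0.18, with 14 of 17 higher (adjusted p = 8.83e-05; adjusted p = 0.246 with an estimated correlation), with the fibroblast growth factor receptor gene Fgfr3 at 0.51 ± 0.15 and the glutamate transporter gene Slc1a3 at 0.45 ± 0.17. Erythrocyte markers fell, with all 4 lower and a median of -0.52 (adjusted p = 0.0261; adjusted p = 0.261 with an estimated correlation), with the globin gene Hbb-b2 at -0.71 ± 0.26. The astrocyte, cholesterol and VTA-enriched calls held without any 1 array, although without SN control array 1 the last 2 medians were -0.14 and 0.13, and the astrocyte median was 0.12 without array 3 of the 2 day group. The immediate early call ended without SN control array 1 (0.034) or 2 day array 3 (0.15), the erythrocyte call without SN control array 2 (-0.37) or 2 day array 1 (-0.52), and the ribosomal call without 2 day array 1 (0.046), while without SN control array 1 its median turned to -0.036.

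Single genes in SN after 2 days stopped just short of the threshold. Limma called 0 of 18193 genes, with 1210 at an unadjusted p under 0.05. Genes sharing the smallest adjusted p, 0.0637, without overlap between arrays included Per2, a component of the circadian clock, at 1.03 ± 0.17, the flavin monooxygenase gene Fmo2 at 1.08 ± 0.17, the triadin gene Trdn at 1.02 ± 0.16 and Wdfy1, a phosphoinositide-binding protein gene, at -0.81 ± 0.14. Probe sets of a gene differed in size, from 0.058 to 2.33 for Fmo2, from 0.039 to 1.80 for Trdn and from -1.70 to 0.042 for Wdfy1. The extracellular matrix gene Reln was at 0.79 ± 0.16 (adjusted p = 0.221), and Milr1 and Tpbg were at -1.05 ± 0.20 and -0.91 ± 0.18. Array weights gave 20 genes, a repeated quantile normalisation 6, omission of the 2 arrays of widest spread 1, omission of SN control array 1 alone 1, and omission of SN control array 3 alone 3.

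After 10 days of MPTP, 1 gene passed in SN. AA388235, a gene known here by a clone name only, rose 2.70-fold (log2 1.43 ± 0.20, adjusted p = 0.0404), with no overlap between the 3 arrays of each group and both probe sets higher, by 1.01 and 1.86. H2-K1, which encodes a class I histocompatibility antigen, was at 1.38 ± 0.21 (adjusted p = 0.0522), with its 4 probe sets from 0.029 to 3.62. The related H2-D1 was at 0.71 ± 0.16 (adjusted p = 0.475), with probe sets from -0.54 to 2.51 and 5 of 9 in the direction of the mean. E4f1, a transcription factor gene, was at -1.35 ± 0.24 and Flywch2 at -1.03 ± 0.20. Limma gave 1013 genes an unadjusted p under 0.05.

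The call of AA388235 in SN was lost when SN control array 1, 2 or 3, or 10 day array 1 or 2, was left out, with differences of 1.25 to 1.49 and adjusted p of 0.0986 to 0.213. Counts were 0 in a fit of only the 2 groups and after a repeated quantile normalisation, 7 over single probe sets, 4 with the probe set of largest SD, 3 with array weights and 2 with a random block. Without the 2 arrays of widest spread 1 gene passed, and it was not AA388235.

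Identity genes fell in SN after 10 days too, with a median of -0.56 and 25 of 26 lower (adjusted p = 2.73e-06; adjusted p = 0.411 with an estimated correlation; exact permutation p = 0.1 for the mean). None of the members passed, over all genes or adjusted over the list alone. Th was at -0.86 ± 0.52, Slc6a3 at -0.42 ± 0.37, Slc18a2 at -0.41 ± 0.43, Ddc at -0.34 ± 0.31, Foxa1 at -0.79 ± 0.30 and the gamma-synuclein gene Sncg at -1.11 ± 0.42. SN-enriched genes fell by a median of 0.458 on the log2 scale, with 15 of 17 lower (adjusted p = 0.000431; adjusted p = 0.445 with an estimated correlation), and VTA-enriched genes rose by 0.31, with 18 of 22 higher (adjusted p = 0.00276; adjusted p = 0.305 with an estimated correlation). The identity call held without any 1 array, at -0.36 without SN control array 1. Without that array Th was at -0.57, Slc6a3 at -0.24 and Slc18a2 at -0.14. The SN-enriched call then ended (-0.27), and the VTA-enriched median was then 0.13.

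Chaperone and sterol genes were also lower in SN after 10 days. Unfolded protein response genes had a median of -0.14, with 22 of 28 lower (adjusted p = 0.0306; adjusted p = 0.384 with an estimated correlation), and Sdf2l1, an endoplasmic reticulum chaperone partner, was at -0.66 ± 0.23, and at -0.395 without SN control array 3. Heat shock chaperones had a median of -0.11, with 19 of 24 lower (adjusted p = 0.0331; adjusted p = 0.305 with an estimated correlation; fry adjusted p = 0.000219), with the small heat shock protein gene Hspb1 at -0.55 ± 0.27. Cholesterol synthesis genes had a median of -0.21, with 16 of 19 lower (adjusted p = 0.019; adjusted p = 0.445 with an estimated correlation). The unfolded protein response call ended without SN control array 3 or 10 day array 2 or 3 (-0.105 to -0.082), the heat shock call without SN control array 1 or 3 or 10 day array 2 or 3 (-0.12 to -0.085), and the cholesterol call without SN control array 1 (-0.14) or 10 day array 2 (-0.12).

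Markers of other cells moved beside these groups in SN after 10 days. Astrocyte markers were at 0.099, with 13 of 17 higher (adjusted p = 0.019; adjusted p = 0.425 with an estimated correlation), and the water channel gene Aqp4 was at 0.59 ± 0.22. Oligodendrocyte markers were at -0.145, with 15 of 17 lower (adjusted p = 0.0306; adjusted p = 0.706 with an estimated correlation), and all 4 erythrocyte markers were lower, at -0.46 (adjusted p = 0.04997; adjusted p = 0.384 with an estimated correlation). Ependyma and choroid plexus markers were at 0.54, with 7 of 10 higher (adjusted p = 0.019; adjusted p = 0.363 with an estimated correlation). Among them the transthyretin gene Ttr, abundant in choroid plexus, was at 4.76 ± 2.30, with an SD of 3.76 between the 10 day arrays. Omissions ended each of these calls. They were SN control array 1 (0.105) and 10 day array 3 (0.044) for astrocytes, SN control arrays 2 and 3 and 10 day arrays 2 and 3 (-0.23 to -0.035) for oligodendrocytes, SN control array 2 and 10 day arrays 1 and 2 (-0.31 to -0.29) for erythrocytes, and SN control array 1 (0.48) and 10 day array 1 (0.47) for ependyma. The ependyma median was 0.23 without 10 day array 3.

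In VTA after 2 days of MPTP, 2 genes passed. Wdfy1 fell 2.19-fold (log2 -1.13 ± 0.14, adjusted p = 0.00515), and Capsl, which encodes a calcium-binding protein, rose 5.57-fold (log2 2.48 ± 0.37, adjusted p = 0.0414), both with no overlap between the 3 arrays of each group. Probe sets of Wdfy1 ranged from -1.97 to 0.015, and the SD of Capsl between control arrays was 0.67. Among genes not passing were the purinergic receptor gene P2rx7 at -1.20 ± 0.20 (adjusted p = 0.0982), the inducible heat shock protein 70 gene Hspa1b at 1.31 ± 0.24 and Noxred1 at 1.82 ± 0.35 (adjusted p = 0.167 for each). Th was at -0.79 ± 0.52, Slc6a3 at -0.46 ± 0.37, Slc18a2 at -0.73 ± 0.43 and Ddc at -0.40 ± 0.31. With 1 array left out they ran from -1.45 to -0.43 for Th, -0.97 to -0.13 for Slc6a3, -1.24 to -0.29 for Slc18a2 and -0.85 to -0.16 for Ddc, each lowest without VTA control array 1.

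Limma gave 1467 genes an unadjusted p under 0.05 in VTA after 2 days. The count of 2 became 0 in a fit of only the 2 groups, with the probe set of largest SD and without VTA control array 2, and 1 after a repeated quantile normalisation, without VTA control array 1, without 2 day array 1 and without the 2 arrays of widest spread, where Wdfy1 was the gene kept. It became 6 over single probe sets, and 4 without VTA control array 3. Wdfy1 lost its call without VTA control array 2 (-1.03, adjusted p = 0.0518), and Capsl without VTA control array 1 or 2 or any 1 of the 2 day arrays (2.16 to 2.69, adjusted p of 0.0669 to 0.181).

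Identity genes fell as a group in VTA after 2 days, with a median of -0.60 and 25 of 26 lower (adjusted p = 3.16e-07; adjusted p = 0.487 with an estimated correlation), and none passed singly or adjusted over the list alone. Foxa1 was at -0.86 ± 0.30 and Ret at -0.805 ± 0.32. The exact permutation p of the list mean was 0.3, and control means ran from -0.45 to 0.62. SN-enriched genes fell by 0.443 in the median on the log2 scale, with 15 of 17 lower (adjusted p = 0.00166; adjusted p = 0.582 with an estimated correlation). The identity call held without any 1 array, with a median of -0.97 without VTA control array 1. The SN-enriched call ended without VTA control array 2 (-0.23) or 2 day array 1 (-0.13).

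Oligodendrocyte markers fell in VTA after 2 days, with a median of -0.33 and all 17 lower (adjusted p = 3.16e-07; adjusted p = 0.477 with an estimated correlation; exact permutation p = 0.1 for the mean). The myelin gene Mog was at -1.002 ± 0.23 and Fa2h, a fatty acid hydroxylase of myelin lipid synthesis, at -0.87 ± 0.20, and 3 members passed adjusted over the list alone, against 0 over all genes. Precursor markers fell, with a median of -0.45 and 6 of 7 lower (adjusted p = 0.00751; adjusted p = 0.450 with an estimated correlation), with the transcription factor gene Olig2 at -0.76 ± 0.20 and 2 members past the threshold adjusted over the list alone. Markers of microglia (median -0.18, 16 of 19 lower, adjusted p = 0.0091), astrocytes (-0.13, 14 of 17 lower, adjusted p = 0.0283) and endothelium (-0.18, 17 of 21 lower, adjusted p = 0.0396) were lower too, each with adjusted p = 0.582 with an estimated correlation. The oligodendrocyte call held without any 1 array. The precursor call ended without VTA control array 1 (-0.36), the astrocyte call without that array (-0.056) or 2 day array 1 (-0.14), the microglia call without VTA control array 2 (-0.18) or 2 day array 1 (-0.14), and the endothelial call without any 1 control array or 2 day array 1 or 2 (-0.23 to -0.11).

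Smaller shifts in VTA after 2 days passed in 3 further lists. Neurotrophic factors and receptors were at -0.155, with 21 of 30 lower (adjusted p = 0.0435; adjusted p = 0.487 with an estimated correlation), interferon-stimulated genes at -0.15, with 22 of 31 lower (adjusted p = 0.049; adjusted p = 0.783 with an estimated correlation), and cholesterol synthesis genes at -0.16, with 15 of 19 lower (adjusted p = 0.0435; adjusted p = 0.582 with an estimated correlation). Their calls ended under most omissions: VTA control array 1 or 2 or 2 day array 1 or 3 for neurotrophic genes (-0.24 to -0.092), VTA control array 1 or 2 or any 2 day array for interferon-stimulated genes (-0.21 to -0.095), and VTA control array 2 or 3 or 2 day array 1 or 3 for cholesterol genes (-0.19 to -0.11).

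In VTA after 10 days, 2 genes passed, and AA388235, the gene called in SN, was among them. H2-K1 rose 2.63-fold (log2 1.39 ± 0.21) and AA388235 2.59-fold (log2 1.37 ± 0.20), with adjusted p = 0.0454 for each and no overlap between the 3 arrays of each group. The probe sets of H2-K1 ranged from 0.18 to 3.46, and those of AA388235 were at 0.96 and 1.79. Not passing were Ucma, a secreted cartilage matrix protein gene, at 2.18 ± 0.43, the growth factor gene Hbegf at 0.63 ± 0.13 and the defensin gene Defa3 at -1.28 ± 0.22 (adjusted p = 0.183). Th was at -0.13 ± 0.52 (-0.79 to 0.235 with 1 array left out) and Slc6a3 at -0.079 ± 0.37 (-0.59 to 0.197), and the identity list was not called, with a median of -0.23 (adjusted p = 0.0894). Means of this list ran from -0.445 to 0.616 on the control arrays and from -0.214 to 0.514 after 10 days. This spread leaves open whether and by how much the identity genes fell here.

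Unfolded protein response genes were lower in VTA after 10 days, with a median of -0.12 and 22 of 28 lower (adjusted p = 0.00546; adjusted p = 0.449 with an estimated correlation). The endoplasmic reticulum chaperone gene Hspa5 was at -0.38 ± 0.12 and Xbp1, a transcription factor of this response, at -0.57 ± 0.22. Oligodendrocyte markers were lower beside them, with a median of -0.25 and 15 of 17 lower (adjusted p = 0.00489; adjusted p = 0.810 with an estimated correlation), with Mog at -0.64 ± 0.23. The former call ended without VTA control array 1 (-0.077) or 10 day array 2 (-0.083), the latter without VTA control array 2 (-0.12) or 10 day array 2 (-0.19).

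Limma gave 985 genes an unadjusted p under 0.05 in VTA after 10 days. The count of 2 became 0 in a fit of only the 2 groups, after a repeated quantile normalisation, with array weights, with a random block, without the 2 arrays of widest spread, and without VTA control array 1 or 3 or 10 day array 1 or 3. It became 4 with the probe set of largest SD. Both genes kept their calls without 10 day array 2. Without VTA control array 2 both lost them and 3 other genes passed. Over all omissions that ended a call, the difference ran from 1.22 to 1.49 for H2-K1 and from 1.17 to 1.44 for AA388235.

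The difference between the VTA and SN responses was tested directly. After 2 days limma called 0 genes, with 601 at an unadjusted p under 0.05, and after 10 days 0 genes, with 576, where 910 are due to chance. After 2 days every alternative also gave 0; after 10 days omission of the 2 arrays of widest spread gave 1 and the others 0. Genes sharing the smallest adjusted p after 2 days, 0.701, included Zfp112 at 1.09 ± 0.20, Zwilch at 2.19 ± 0.44 and P2rx7 at -1.38 ± 0.28, whose probe sets ranged from -2.82 to -0.43. Between VTA and SN controls these genes differed the other way, at -0.85 ± 0.14, -1.81 ± 0.31 and 0.85 ± 0.20. For them a different response cannot be told apart from a difference between the control groups. After 10 days Defa3 was at -1.63 ± 0.32 and the glutamate receptor gene Grin2c at 0.90 ± 0.22, with an adjusted p = 1 for each. The difference of responses of Th was 0.50 ± 0.74 after 2 days and 0.73 ± 0.74 after 10 days, and that of Otx2 was -0.92 ± 0.45 and -1.12 ± 0.45. Without VTA control array 1 the values of Th were -0.16 and 0.074. The arrays of both regions may share mice, in which case p-values of this difference without a block may be too large.

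At the level of lists, the responses to 2 days of MPTP differed by camera in VTA-enriched genes and in markers of other cells. In 2 of these lists 1 control group stood apart. The VTA-enriched mean was -0.335 in SN controls and -0.069 to 0.085 in the other groups. The precursor mean was 0.262 in VTA controls and -0.117 to 0.007 in the others. For these lists a different response cannot be told apart from a difference between the control groups. Astrocyte markers responded lower in VTA than in SN, with a median difference of -0.335 and all 17 members lower (adjusted p = 5.08e-08; adjusted p = 0.136 with an estimated correlation), with the connexin 30 gene Gjb6 at -0.76 ± 0.28 and S100b at -0.67 ± 0.25. The difference was called without any 1 array. The astrocyte mean was -0.079 ± 0.048 (SD) in SN controls and 0.072 ± 0.088 in VTA controls, against 0.1 ± 0.118 and -0.117 ± 0.06 after 2 days. Part of the astrocyte difference therefore lies between the control groups. A different share of astrocyte material in the captures was not tested here. VTA-enriched genes also responded lower in VTA, with a median of -0.35 and 19 of 22 lower (adjusted p = 0.00137; adjusted p = 0.153 with an estimated correlation), as did oligodendrocyte markers (-0.22, 15 of 17 lower, adjusted p = 0.00397; adjusted p = 0.758 with an estimated correlation), their precursors (-0.38, all 7 lower, adjusted p = 0.00791; adjusted p = 0.153 with an estimated correlation), with Olig2 at -0.61 ± 0.29, and endothelial markers (-0.285, 16 of 21 lower, adjusted p = 0.0434; adjusted p = 0.758 with an estimated correlation). Each of these 4 calls ended when certain single arrays were left out, in the precursor list with little change of the median. The VTA-enriched call ended without VTA 2 day array 1 (-0.28), and its median was -0.22 without VTA control array 1. The oligodendrocyte call ended without SN control array 1, VTA control array 2 or VTA 2 day array 2 (-0.15 to -0.11), the precursor call without SN control array 2, VTA control array 1 or VTA 2 day array 2 (-0.38 to -0.35), and the endothelial call without SN control array 1, SN 2 day array 1 or 3, VTA control array 2 or 3, or VTA 2 day array 1 or 2 (-0.285 to -0.105). After 10 days no list was called.

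Regions were also compared within each MPTP group. After 2 days limma called 0 genes, with 508 at an unadjusted p under 0.05, and after 10 days 0 genes, with 544, and every alternative gave 0. After 2 days Trdn was at -0.70 ± 0.16 and the calpain gene Capn9 at 1.57 ± 0.44 (0.90 to 2.24 with 1 array left out), while Th was at 0.045 ± 0.52 (-0.37 to 0.26 with 1 array left out) and Otx2 at -0.12 ± 0.32, whose sign turned after a repeated quantile normalisation (0.058) and with array weights (0.21). After 10 days Tacr3 was at 1.41 ± 0.36, the gastrin-releasing peptide gene Grp at 0.76 ± 0.31, the methyltransferase gene Vcpkmt at -0.77 ± 0.14 (adjusted p = 0.698) and Th at 0.28 ± 0.52 (-0.11 to 0.63). The arrays of both regions may share mice.

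After 2 days all 17 astrocyte markers were lower in VTA than in SN, with a median of -0.205 (adjusted p = 1.79e-06; adjusted p = 0.260 with an estimated correlation), and this call held without any 1 array. Lists of microglia (-0.17, 14 of 19 lower) and endothelium (-0.17, 16 of 21 lower) had adjusted p = 0.00671 each (adjusted p = 0.822 with an estimated correlation). The oligodendrocyte list was at -0.105, with 15 of 17 lower (adjusted p = 0.0368; adjusted p = 0.884 with an estimated correlation), and the ribosomal list at -0.079, with 41 of 48 lower (adjusted p = 0.00671; adjusted p = 0.884 with an estimated correlation). After 10 days complex I genes were lower in VTA, at -0.091 with 28 of 35 lower (adjusted p = 0.046; adjusted p = 0.908 with an estimated correlation), and ribosomal genes at -0.093 with 34 of 48 lower (adjusted p = 0.021; adjusted p = 0.908 with an estimated correlation). Without VTA 2 day array 1 the endothelial (-0.096), microglia (-0.065) and ribosomal (0.007) calls after 2 days ended. The other omissions that ended a call there were VTA 2 day array 2 for endothelium (-0.16) and oligodendrocytes (-0.048), SN 2 day array 3 for microglia (-0.052) and oligodendrocytes (-0.07), and VTA 2 day array 3 for oligodendrocytes (-0.079). After 10 days SN array 3 or VTA array 1 or 2 ended the ribosomal call (-0.068 to -0.054), and SN array 1 or 3 or VTA array 1 or 2 the complex I call (-0.088 to -0.062).

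Within SN, 10 days of MPTP were compared with 2 days. Passing genes numbered 3, each with no overlap between the 3 arrays of each group. AA388235 rose 2.96-fold (log2 1.56 ± 0.20) and H2-K1 rose 2.90-fold (log2 1.54 ± 0.21, probe sets 0.034 to 3.69), each with adjusted p = 0.0135, and Fmo2 fell 2.16-fold (log2 -1.11 ± 0.17, probe sets -2.31 to 0.017, adjusted p = 0.0351). Among genes not passing were Per2 at -0.97 ± 0.17, Hspa1b at -1.33 ± 0.24 and Wdfy1 at 0.75 ± 0.14 (adjusted p = 0.106 for each), whose probe sets ranged from -0.115 to 1.52. The lipid droplet gene Plin4 was at -1.34 ± 0.27. Limma gave 549 genes an unadjusted p under 0.05, and the count of 3 became 9 over single probe sets and after a repeated quantile normalisation, 24 with array weights, 7 without the 2 arrays of widest spread and 0 in a fit of only the 2 groups. With the probe set of largest SD Fmo2 was not called. The count became 0 without any 1 of the 2 day arrays or 10 day array 1, 1 (H2-K1) without 10 day array 2 and 1 (AA388235) without 10 day array 3.

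Within VTA, 6 genes passed between 10 and 2 days of MPTP, each with no overlap between the 3 arrays of each group. Wdfy1 rose 2.045-fold (log2 1.03 ± 0.14, adjusted p = 0.017, probe sets 0.023 to 2.01) and Fbxw17, an F-box protein gene, 2.92-fold (log2 1.55 ± 0.22, adjusted p = 0.0227). H2-K1 rose by 1.34 ± 0.21 and AA388235 by 1.27 ± 0.20, and Plin4 and Per2 fell, with -1.76 ± 0.27 and -1.14 ± 0.17 on the log2 scale (adjusted p = 0.0291 for these 4). Hspa1b was at -1.36 ± 0.24 (adjusted p = 0.0638). Limma gave 1154 genes an unadjusted p under 0.05, and the count of 6 became 16 over single probe sets, 10 with the probe set of largest SD and 0 in a fit of only the 2 groups. Of the 6, AA388235 was not called with the probe set of largest SD, with a random block or after a repeated quantile normalisation, Plin4 not after the latter, and Plin4 and Per2 not without the 2 arrays of widest spread. The count became 0 without 2 day array 1 or 10 day array 1 or 2, 1 without 10 day array 3, 3 without 2 day array 2, and 5 without 2 day array 3, of which 2 were among the 6.

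**Figure D2:**
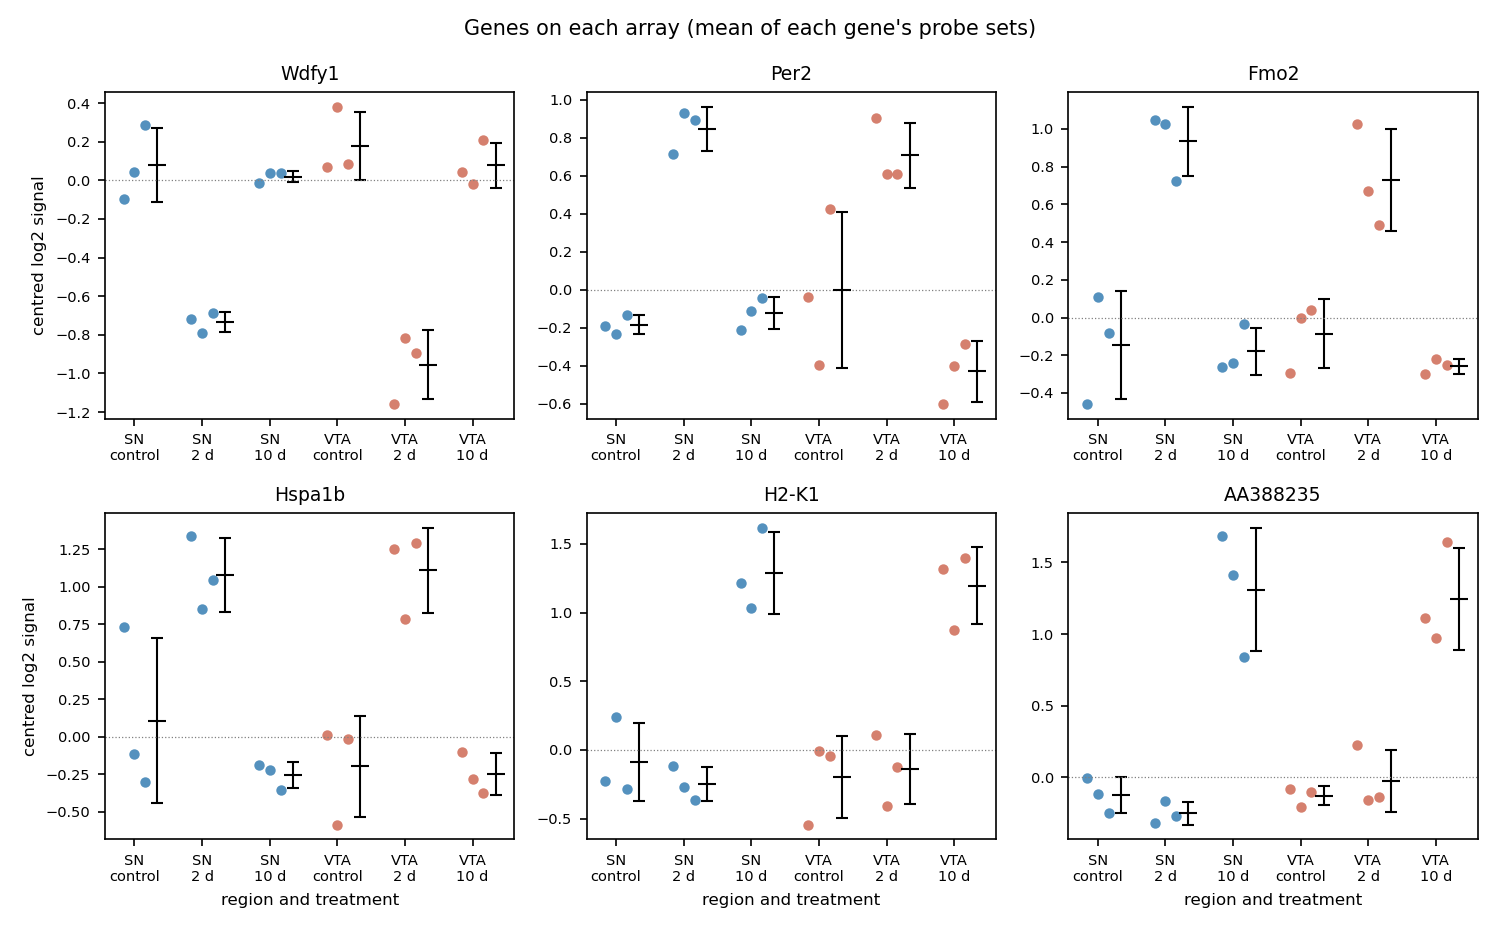
Centred log2 signal (vertical axis, log2 units relative to the median of 18 arrays) of Wdfy1, Per2, Fmo2, Hspa1b, H2-K1 and AA388235 on each array, for the 6 groups of region and treatment (horizontal axis); points are arrays and black bars are means ± SD of 3 arrays. H2-K1 lies between 0.87 and 1.62 on the 6 arrays of the 10 day groups and at 0.238 or lower on the others, and Wdfy1 lies between -1.16 and -0.69 on the 6 arrays of the 2 day groups and at -0.096 or higher on the others.

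Chaperone genes were lower after 10 than after 2 days of MPTP in both regions. Heat shock chaperones had a median of -0.10 in SN, with 21 of 24 lower (adjusted p = 4.77e-05; adjusted p = 0.00687 with an estimated correlation; fry adjusted p = 8.03e-06), and of -0.092 in VTA, with 18 of 24 lower (adjusted p = 0.00298; adjusted p = 0.0509 with an estimated correlation). Unfolded protein response genes had a median of -0.13 in SN, with 20 of 28 lower (adjusted p = 1.45e-05; adjusted p = 0.0262 with an estimated correlation), and of -0.12 in VTA, with 17 of 28 lower (adjusted p = 0.00298; adjusted p = 0.205 with an estimated correlation). Hspa5 was at -0.50 ± 0.12 in SN and -0.52 ± 0.12 in VTA, Manf, a secreted endoplasmic reticulum stress protein, at -0.61 ± 0.15 in SN, Sdf2l1 at -1.06 ± 0.23 in VTA, the co-chaperone gene Dnajb1 at -0.46 ± 0.15 in SN and Hspb1 at -0.90 ± 0.27 in VTA. No member passed over all genes. Adjusted over the list alone, 1 heat shock and 4 unfolded protein response genes passed in SN and 2 and 5 in VTA. Among the 11 planned comparisons, these 2 lists in SN were the only calls that held with an estimated correlation. The exact permutation p of the list mean was 0.1 in each case, and the heat shock call held without any 1 array in both regions. The unfolded protein response call held so in SN, with a median of -0.073 without 2 day array 3. In VTA it ended without 2 day array 2 (-0.075), and its median was -0.046 without 10 day array 2.

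Identity genes were higher after 10 than after 2 days, by a median of 0.32 in SN, with 24 of 26 higher (adjusted p = 0.000417; adjusted p = 0.664 with an estimated correlation), and 0.36 in VTA, with 23 higher (adjusted p = 0.00298; adjusted p = 0.589 with an estimated correlation). Interferon-stimulated genes, a list that holds H2-K1, were higher by 0.25 in SN, with 24 of 31 higher (adjusted p = 0.000195; adjusted p = 0.609 with an estimated correlation), and 0.15 in VTA, with 21 higher (adjusted p = 0.0183; adjusted p = 0.589 with an estimated correlation). Of their members, 1 passed over all genes in each region, and 2 in SN and 3 in VTA adjusted over the list alone. Immediate early genes were lower in SN, at -0.26 with 20 of 22 lower (adjusted p = 0.000417; adjusted p = 0.609 with an estimated correlation). In SN the identity (0.16) and interferon (0.13) calls ended without 10 day array 3, and the immediate early call without 10 day array 1 (-0.15). In VTA the identity call ended without 2 day array 1 (0.16) or 10 day array 3 (0.18), and the interferon call without 2 day array 2 (0.29), 2 day array 3 (0.14) or 10 day array 3 (0.063).

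In VTA, 6 further lists were called between 10 and 2 days, each with adjusted p = 0.589 with an estimated correlation. Complexes II to V were at -0.081, with 34 of 39 lower (adjusted p = 0.0186), and proteasome subunits at -0.081, with 26 of 33 lower (adjusted p = 0.0229). Cholesterol synthesis genes were at 0.11, with 16 of 19 higher and 1 past the threshold adjusted over the list alone (adjusted p = 0.0206). Markers of microglia were at 0.23, with 14 of 19 higher (adjusted p = 0.00449), of oligodendrocytes at 0.21, with 12 of 17 higher (adjusted p = 0.0344), and of endothelium at 0.28, with 15 of 21 higher (adjusted p = 0.0249). Each call ended when certain single arrays were left out, in some lists with a median as large as before. Those whose omission ended it were 2 day array 2 or 3 or 10 day array 2 for complexes II to V (-0.095 to -0.049), 2 day array 2 or 3 or 10 day array 1 or 2 for the proteasome (-0.077 to -0.038), 2 day array 1 or 3 or 10 day array 3 for cholesterol genes (0.008 to 0.106), 2 day array 1 (0.14) or 10 day array 3 (0.23) for microglia, 2 day array 1 or 2 or 10 day array 1 or 3 for endothelium (0.13 to 0.27), and 2 day array 3 or 10 day array 1 or 3 for oligodendrocytes (0.14 to 0.18), whose median turned to -0.038 without 2 day array 2.

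Responses were then set against each other across genes, which are not independent replicates. In SN, the differences after 2 and 10 days correlated with a Pearson r of 0.663 and a Spearman rho of 0.633, where 100 simulations of unchanged groups against shared controls gave 0.501; 72.8% of genes had the same sign, against 66.7% simulated. The covariance was 0.046 against 0.032 simulated, a difference of 0.014. In VTA r was 0.521 (rho 0.492) against 0.5 simulated, with 67.7% of the same sign against 66.6%, and a covariance of 0.038 against 0.032, a difference of 0.006. The 3 control arrays of a region cannot be split into independent sets of at least 2 each, and part of any excess may come from them. Between regions, where no array is shared, r was 0.354 (rho 0.282) after 2 days, with 58.8% of the same sign against 50.1% simulated, and 0.265 (rho 0.21) after 10 days, with 57% of the same sign. Those simulations treat SN and VTA arrays as independent. With arrays of the same number correlated as observed, a simulation added after the correlations were seen, unchanged groups gave r of 0.163 after 2 days, with 55.2% of the same sign, and 0.249 after 10 days, with 58%, so that the value after 10 days is close to that of unchanged groups. AA388235 was the shared call of both regions after 10 days, where independent lists would share 0.00011 genes. For 10 against 2 days, r between regions was 0.344 (rho 0.251), against 0.25 in that simulation, with 57.6% of the same sign against 58%, and AA388235 and H2-K1 were shared, against 0.00044 genes for independent lists. The arrays of both regions may share mice.

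The remaining lists were called in none of the 11 comparisons. In the order SN after 2 days, SN after 10 days, VTA after 2 days and VTA after 10 days, medians against saline were -0.001, -0.037, -0.033 and -0.076 for antioxidant genes, -0.10, -0.015, -0.063 and 0.018 for apoptosis genes, and 0.020, -0.050, 0.001 and 0.013 for synaptic vesicle genes. They were 0.022, -0.017, 0.077 and 0.060 for ion channels and calcium pumps, -0.10, -0.046, -0.030 and 0.056 for familial Parkinson disease genes, 0.027, 0.040, -0.006 and 0.029 for axon guidance genes, and -0.003, -0.068, -0.068 and -0.011 for lysosome and autophagy genes. GABA neuron markers were at -0.039, -0.104, 0.016 and 0.015, and markers of glutamate, cholinergic and serotonin neurons at -0.075, -0.14, -0.086 and -0.28. This last list had means of opposite sign to its medians in SN after 2 days (0.15) and 10 days (0.017) and in VTA after 2 days (0.016). The same held for antioxidant (0.013) and synaptic vesicle genes (-0.023) in SN after 2 days, and for GABA neuron markers in VTA after 2 days (-0.040) and 10 days (-0.004). Ion channels in SN after 10 days had a negative mean and median and a positive direction in camera. The smallest adjusted p among these lists was 0.0823, for antioxidant genes in VTA after 10 days.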

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

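Of the tests below, the comparison of other-cell lists, the interferon test and the test of neighbouring genes were chosen after the result was seen, the tests of a deviant array, of clock genes and of glucocorticoid genes were written down before their own results, and the count of clock genes and the counts of neighbouring genes without Mog or list members were added after the first values were seen.

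The fall of dopamine neuron identity genes in SN after 2 days of MPTP is what injury by a toxin of dopamine neurons would give, and a larger share of other cells in the captures would lower the same genes. More material of every other cell type would raise all their markers, but the mean shift was 0.18 ± 0.079 for astrocytes, -0.071 ± 0.154 for microglia, -0.193 ± 0.153 for oligodendrocytes and -0.04 ± 0.155 for endothelium. The largest gap, astrocytes minus oligodendrocytes, was 0.373 ± 0.158, which argues against a general rise of other-cell material as the sole cause, although it lies only just beyond 2 SE and is the extreme of 4 lists. More astrocyte material alone was not excluded. A single deviant array would be likely to end the fall when left out, and the median without SN control array 1, the value nearest 0, was -0.804 against -0.962 with all arrays.

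H2-K1 and AA388235 were higher on all 10 day arrays of both regions, and 10 days of MPTP, an interferon response or a genomic segment that differs between the mice of the groups could each give this. Interferon-stimulated genes outside the major histocompatibility complex had a mean shift of -0.033 ± 0.122 (25 genes) against saline over both regions. This is below a bound of 0.35 and argues against an interferon response in that comparison, as far as these genes were detected. How many were detected is unknown, because the values hold no level, and undetected genes would draw the mean towards 0. Against 2 days of MPTP the whole interferon list was called higher by camera in both regions. Its genes outside the complex were not tested there. In the assembly GRCm38.p6 no tested gene lies between H2-K1 and AA388235, and 9 of the 200 nearest tested neighbours of H2-K1 had p under 0.01 (Abhd16a, Cdkn1a, Cyp4f15, Mog, Ring1, Tnxb, Wdr46, Zfp57 and Zfp871), where 10000 random windows had a median of 4 and a 95th percentile of 8. Mog belongs to the oligodendrocyte list, which was lower after 10 days (median -0.22 over both regions), and without it the count is 8, as it is when members of all fixed lists are left out of every window, where 8.77% of random windows had as many. H2 genes and AA388235 were left out of these counts. E4f1 (-1.14 ± 0.17) and Flywch2 (-0.93 ± 0.14), lower against saline over both regions, lay outside the 200 neighbours. H2-D1 was higher in that comparison (0.68 ± 0.11, limma adjusted p = 0.0467, adjusted p = 0.0796 with a random block). Probe sets ranged from 0.197 to 3.54 for H2-K1 and from -0.67 to 2.38 for H2-D1, which these counts do not weigh. A segment that differs between animals is therefore left open, and MPTP and the origin of the mice cannot be told apart here.

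Per2, Fmo2, Plin4 and Hspa1b were higher on the 2 day arrays of both regions than after saline or 10 days of MPTP. This may reflect MPTP, fewer days of injection, another time of day at collection, or higher glucocorticoid signalling. Saline was given for 10 days only, so MPTP for 2 days and fewer days of injection cannot be told apart. Signed by the direction predicted, 12 other clock genes had a mean shift of 0.091 ± 0.058. This is more than 2 SE below the bound of 0.25 written beforehand, and by that bound the mean argues against another time of day. A count added afterwards goes the other way, with 7 of the 12 beyond 2 SE, 6 as predicted and Npas2 against it. As many lay beyond 2 SE in 0.01% of 10000 random lists. The mean and the count disagree, so another time of day is left open. The mean shift of 15 other glucocorticoid genes was 0.17 ± 0.059, with Fkbp5 at 0.321 ± 0.143 and Sgk1 at 0.475 ± 0.236, which fits higher glucocorticoid signalling. That rests on the mean, since 2 of 15 genes lay beyond 2 SE, as in 54.2% of random lists.

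Responses to 2 days of MPTP differed between VTA and SN, by a camera test of the difference itself, in 5 lists. In the VTA-enriched and precursor lists a single control group stood apart from the other groups. There a different response cannot be told apart from a difference between controls. In the astrocyte list part of the difference also lay between the control groups, with means of -0.079 in SN and 0.072 in VTA. The median differences were -0.354 for VTA-enriched genes, -0.335 for astrocyte, -0.219 for oligodendrocyte, -0.381 for oligodendrocyte precursor and -0.285 for endothelial markers, and with an estimated correlation none of the 5 was called (adjusted p = 0.136 or higher). Among probe sets without a single gene name, which no comparison used, 1 passed the threshold in VTA after 2 days of MPTP against saline, at 1.32 ± 0.19 (adjusted p = 0.032).

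Counts of genes were compared with those of other splits of the arrays, with the predictions written down before the splits were run; the comparisons over both regions were themselves chosen after the data were seen. For 3 against 3 arrays 10 splits are too few to decide. In the order real count, highest other count and number of splits with as many, the real one included, they gave 0, 0 and 10 for VTA against SN in controls, 0, 1 and 10 for SN after 2 days, 1, 19 and 2 for SN after 10 days, 2, 1 and 1 for VTA after 2 days, and 2, 0 and 1 for VTA after 10 days. They gave 0, 0 and 10 between regions after 2 days and 0, 1 and 10 after 10 days, and 3, 0 and 1 for 10 against 2 days in SN and 6, 0 and 1 in VTA. Of 100 splits, as many genes were called in 100 for the difference of responses after 2 days (0, highest other 3) and in 100 after 10 days (0, highest other 189). Over both regions they were 1 of 100 for 2 days (16, highest other 1), 3 of 100 for 10 days (7, highest other 78) and 1 of 100 for 10 against 2 days (23, highest other 1). Each set of 100 splits exchanged SN and VTA arrays independently and so ignored any pairing by replicate number. Where arrays share mice, these shares cannot decide.

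The splits with 19, 189 and 78 genes all exchanged SN control array 3 with SN 10 day array 3. Such counts, above the real ones, may come from a structure of the samples other than treatment, which was neither tested nor identified.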

How the results depend on the processing

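Robust eBayes, the probe set of largest SD, omission of the 2 arrays of widest spread, the random block, the comparisons over both regions and the alternatives for correlations between responses were chosen after the data were seen; the other alternatives were fixed before. Of 1848 alternative values of 118 gene results, 1690 kept direction and side of the threshold, 108 lost a call, 33 gained one and 17 turned in sign. Most of these gene results had not passed in the main analysis and so had no call to lose. The share kept is therefore no measure of how well the gene calls hold. Of 650 alternative values of 62 list results, 381 kept both, 263 lost the call and 6 turned in sign. Correlations between responses moved within 0.559 to 0.78 for 2 and 10 days in SN, 0.431 to 0.63 in VTA, 0.271 to 0.392 between regions after 2 days and 0.185 to 0.295 after 10 days, against 0.163 and 0.249 for unchanged groups with correlated array numbers. A stricter level filter, the probe set of highest mean and an eBayes trend could not be run, because the values are centred and hold no level. Signal over background is unknown for the same reason. With an array left out, a group has 2 arrays. The cause was not tested for any change below.

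Array weights gave 20 genes for SN after 2 days (0 in the main analysis), 3 for SN after 10 days (1), 0 for VTA after 10 days (2), 24 for 10 against 2 days in SN (3), and over both regions 130 for 2 days (16) and 125 for 10 against 2 days (23). A repeated quantile normalisation gave 6 for SN after 2 days, 0 for SN after 10 days, 1 for VTA after 2 days (2), 0 for VTA after 10 days and 9 for 10 against 2 days in SN. All probe sets tested singly gave 7 for SN after 10 days, 6 for VTA after 2 days, 9 for 10 against 2 days in SN and 16 in VTA (6). A fit of only the groups compared gave 0 for SN after 10 days, VTA after 2 days, VTA after 10 days, and 10 against 2 days in SN and in VTA. The probe set of largest SD gave 4 for SN after 10 days, 0 for VTA after 2 days, 4 for VTA after 10 days and 10 for 10 against 2 days in VTA. Without the 2 arrays of widest spread the counts were 1 for SN after 2 days, 1 for VTA after 2 days, 0 for VTA after 10 days, 7 for 10 against 2 days in SN, 1 for the difference of responses after 10 days (0) and 14 for 10 days over both regions (7). The random block gave 2 for SN after 10 days, 0 for VTA after 10 days, and over both regions 6 for 2 days and 2 for 10 days.

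The labels state no pairing by replicate number. Still, 8 of 9 SN arrays correlated best with the VTA array of their own number, a hint from the data and not the design. With the replicate block, counts were 0 for SN after 10 days, 4 for VTA after 2 days, 0 for VTA after 10 days and 32 for 2 days over both regions, and for 10 against 2 days in SN 3, with Hspa1b in place of Fmo2. The block ended the calls of interferon-stimulated (adjusted p = 0.0645) and neurotrophic genes (adjusted p = 0.0609) in VTA after 2 days and no other list call; comparisons between regions again gave 0 genes.

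With 1 array left out, counts ran from 0 to 3 for SN after 2 days, 0 to 1 for SN after 10 days, 0 to 4 for VTA after 2 days, 0 to 3 for VTA after 10 days, 0 to 1 for 10 against 2 days in SN and 0 to 5 in VTA, and over both regions from 2 to 51 for 2 days, 2 to 11 for 10 days and 13 to 24 for 10 against 2 days.

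The identity list lost its call with an estimated correlation and with fry in SN after 2 days (-0.962), SN after 10 days (-0.564) and VTA after 2 days (-0.604), where the median itself does not change. With 1 array left out, its medians ran from -1.098 to -0.804, -0.752 to -0.362 and -0.973 to -0.409. Between control regions they ran from -0.476 to 0.153. The ribosomal median in SN after 2 days turned to -0.036 without the 2 arrays of widest spread (-0.036 to 0.139 with 1 array left out), and that between regions after 2 days to 0.007 (-0.147 to 0.007). The oligodendrocyte median for 10 against 2 days in VTA ran from -0.038 to 0.223. Otx2 between regions after 2 days turned from -0.121 to 0.058 after quantile normalisation, 0.213 with array weights and 0.083 without the 2 arrays of widest spread, and ran from -0.309 to 0.106 with 1 array left out. Such ranges crossed 0 for Slc6a3 in VTA after 10 days (-0.588 to 0.197) and for Th in VTA after 10 days (-0.788 to 0.235), between regions in controls (-0.818 to 0.205), after 2 days (-0.373 to 0.264) and after 10 days (-0.112 to 0.629), and in the difference of responses after 2 days (-0.160 to 0.863).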

Other observations

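The comparisons over both regions were chosen after the data were seen. They average the SN and VTA differences over 6 arrays per treatment. SN and VTA arrays may come from the same mice, so that p-values without a block may be too small. Of 100 splits of the arrays, the real one included, 1 gave as many genes as observed after 2 days, 3 after 10 days (real 7, highest other 78) and 1 for 10 against 2 days. These splits exchanged SN and VTA arrays independently, so they give no protection where arrays share mice.

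After 2 days of MPTP, Wdfy1 fell by 0.97 ± 0.095 on the log2 scale over both regions (adjusted p = 0.000366; adjusted p = 0.00149 with a random block), while Fmo2 rose by 0.95 ± 0.12 (adjusted p = 0.00519; adjusted p = 0.00956 with the block). Per2 rose by 0.87 ± 0.12 (adjusted p = 0.01045; adjusted p = 0.0268 with the block), Hspa1b by 1.14 ± 0.17 (adjusted p = 0.01585; adjusted p = 0.0335 with the block) and Capsl by 1.72 ± 0.26 (adjusted p = 0.01585; adjusted p = 0.0382 with the block). Probe sets of Wdfy1 ranged from -1.70 to 0.03 and those of Fmo2 from 0.02 to 2.14. On all 6 arrays of the 2 day groups Wdfy1 was lower, and Per2, Fmo2 and Hspa1b were higher, than on any other array. After 10 days, H2-K1 rose by 1.39 ± 0.15 (adjusted p = 0.00055) and AA388235 by 1.40 ± 0.14 (adjusted p = 0.000544), with adjusted p = 0.00215 with the block for each. Identity genes fell after 2 days, with all 26 lower and a median of -0.707 (adjusted p = 1.04e-14; adjusted p = 0.417 with an estimated correlation), and 18 passed adjusted over the list alone, against 0 over all genes.

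Between 10 and 2 days over both regions, Plin4 fell by 1.55 ± 0.19 on the log2 scale (adjusted p = 0.00143; adjusted p = 0.00308 with the block), Hspa5 fell by 0.51 ± 0.085 (adjusted p = 0.0188; adjusted p = 0.0443 with the block) and H2-D1 rose by 0.79 ± 0.11 (adjusted p = 0.00404; adjusted p = 0.0077 with the block), with probe sets of H2-D1 from -0.17 to 2.60. Heat shock chaperones were lower, with a median of -0.091 and 19 of 24 lower (adjusted p = 1.19e-05; adjusted p = 0.00415 with an estimated correlation), and so were unfolded protein response genes, with a median of -0.102 and 22 of 28 lower (adjusted p = 1.19e-05; adjusted p = 0.027 with an estimated correlation). Of their members 1 and 2 passed over all genes, and 4 and 8 adjusted over the list alone. With the random block the unfolded protein response gene Sdf2l1 no longer passed (limma, adjusted p = 0.0535).

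Limma called 16 genes over both regions after 2 days (12 higher, 4 lower), 7 after 10 days (4 higher, 3 lower) and 23 between 10 and 2 days (11 higher, 12 lower), against 6, 2 and 17 with a random block. Leaving out 1 array moved the first count to 2 (SN control array 2), 4 (SN 2 day array 3), 5 (SN 2 day array 2), 9 (VTA 2 day array 2) or 51 (VTA control array 1). It moved the second to 2 (VTA 10 day array 1 or 2), 3 (SN or VTA control array 3, SN 10 day array 1 or VTA 10 day array 3), 4 (SN control array 2 or SN 10 day array 3) or 11 (VTA control array 2), and the third to 13 (SN 10 day array 2), 14 (SN 2 day array 2) or 15 (SN 10 day array 3). Array weights gave 130 genes for the first and 125 for the third.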
